A study of Homo sapiens with 4 samples.

How the data were processed

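Messenger RNA was measured in Panc1, a cell line from a human pancreatic carcinoma, and in 3 clones of it that resist gemcitabine, a deoxycytidine analogue that blocks DNA synthesis once cells have phosphorylated it. The labels give 1 array for the parental line and 1 array for each of the clones GR1, GR3 and GR4. Per the labels, the parental cells met gemcitabine at 2 ng/ml first and at 30 ng/ml last, the selection took 2 months, the adapted population was cloned by limiting dilution, and the medium held 10% serum. The treatment text in the labels lists the clones as GR1, GR2 and GR3 instead, and the sample titles were followed. The groups were fixed from the titles, with 1 parental array and 3 resistant clones, and no array was left out.

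Each array is a Toray 3D-Gene oligonucleotide chip, hybridized with amplified RNA that carried the single dye Cy5. The deposited scanner files give the median intensity of every spot, before any background subtraction, in the scanner's arbitrary units. The same files hold a column headed as background, also an intensity per the file headers. It follows the spot's own signal, with a log correlation across spots of 0.940, 0.947, 0.966 and 0.966 on the parental, GR1, GR3 and GR4 arrays, so it was not taken as a background measured apart from the spot; whether it is one was not tested. The authors also deposited a table of intensity after background subtraction and scaling. Its values were recomputed from the scanner files as the spot intensity minus the mean of the middle 90% of the 2680 blank spots, divided by 1 factor per array that sets the median to 25. The largest deviation from the deposited values was 0.000206 units, and every empty cell of that table belonged to a spot not above the blank mean plus 2 SD of the blank spots, or to a spot that the scanner marked as faulty.

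The values reported here start from the spot intensities. The plan, with its comparisons, gene lists, rule for named genes and alternatives, was written before the data were examined. It called for the normexp background model with an offset of 50 wherever a file holds a foreground and a background column. Because of this doubt about the background column, the blank mean was subtracted instead, as the authors did, and normexp on the 2 columns became an alternative. That alternative gave 146 limma calls in place of 674 and 321 genes 2-fold apart in all 3 clones in place of 1205. Of the 146 calls 84 were among the 674, and 37.0% of them were higher in the clones, against 53.4% of the 674. The blank mean was 10.1 units on the parental array, 9.50 on GR1, 8.73 on GR3 and 7.84 on GR4. Signals were then quantile normalized between the arrays, raised to a common floor of 1.52 units and put on the log2 scale, where the floor is 0.61. The array holds 24460 gene probes, of which 11 were left out because a spot was marked as faulty. A probe was tested if it lay above the limit, the blank mean plus 2 SD, on the parental array or on all 3 clones. This left 22796 probes, which stand for 16592 genes with a symbol and include 3916 probes with none. A gene with several probes was represented by its probe with the highest mean signal.

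Of the gene probes, 20236 carried 1 gene symbol, 0 carried several and 4224 carried none. The symbol was current in the RefSeq annotation of the human assembly GRCh38.p14 for 17238 probes and was updated through a synonym for 2899. For 98 probes it was a synonym of several genes and for 1 it matched nothing, and these kept the symbol on the array. The annotation served for names and for the order of genes only.

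The clones were compared with the parental array by limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and an adjusted p under 0.05 as threshold. Genes said to rise or fall are those past this threshold, unless adjustment over a list alone is named. The fit has 2 residual degrees of freedom, all from the clones, and the parental array is assumed to vary like them. Errors given with a log2 difference are the standard errors of this fit for 3 clones against 1 parental array. Beside the test, genes at least 2-fold above or below the parental array in all 3 clones were counted, and the same rule was applied with each clone in the parental array's place. For the 39 gene lists, limma's camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry was run beside it, all adjusted over the lists. With an estimated correlation camera tests on the fit's 2 residual degrees of freedom, so a list could hardly pass whatever its correlation. Runs of neighbouring genes were sought with windows of 25 tested genes along each chromosome, by the median log2 difference, against the highest and lowest window medians over 1000 random gene orders, as planned. A first version took bounds that 5% of the random orders pass and found 7 runs, and the planned bounds were restored after that result was seen. For a gene that is not above the limit on the parental array, or is above it on fewer than 2 clones, the fold against the floor is given as a lower bound.

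The rule for named genes takes the 10 largest differences in each direction among genes past the threshold and above the limit on both sides, and up to 5 bounds in each direction. It further takes up to 4 members of each list with the smallest p, 15 genes of gemcitabine handling or other prior interest, 3 genes in each direction for each clone, and 4 genes for each run of neighbours. Of the list members it takes, the text gives those past the threshold and the ones nearest to it in the lists it describes. Genes outside the rule are named to complete a count or to describe lists written later, and the text says so. Loci without a descriptive name were skipped.

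The procedure was tested on simulated data with the same numbers of arrays and genes. With 200 genes changed among 16592, limma called 76% of the genes changed 4-fold and 1% of those changed 2-fold, with 2 unchanged genes called. The rule of a 2-fold difference in all 3 clones found 100% of the genes changed 4-fold, with 22 unchanged genes. With 2000 genes changed 4-fold, limma called 98.3% of them and 57 unchanged genes. In both simulations the changed genes were drawn from the brighter genes, by mean clone signal, so these rates do not cover genes near the floor. A raised list was called, 0 of the 38 other lists were, and the 1 raised run of neighbours was found. The simulated genes varied independently of one another, so false calls of lists whose genes vary together were not tested.

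Alternatives were tried 1 at a time: median scaling, cyclic loess and no normalization between arrays, the authors' table, normexp on the spot and background columns, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, leaving out each clone, an intensity trend or a robust prior in eBayes, other thresholds, camera on ranks, and windows of 15 or 50 genes. Normexp on the blank-subtracted signals, with an offset of 50 and with none, and the looser bounds for runs of neighbours were added after seeing the data. R 4.3.3 with limma 3.58.1 was used, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.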

Results

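Transcripts were measured on 4 arrays, 1 for the parental Panc1 line and 1 for each of the gemcitabine-resistant clones GR1, GR3 and GR4. Of 24460 gene probes, 22594 (92.4%) were above the blank-spot limit on the parental array, 22746 (93.0%) on GR1, 22926 (93.7%) on GR3 and 22379 (91.5%) on GR4. The median signal of these probes above the blank mean was 35.5 intensity units on the parental array, 38.1 on GR1, 35.7 on GR3 and 35.6 on GR4. The number of arrays limits the precision of every value, and the parental line, with 1 array, has no spread of its own. The spots of 1 control probe, Positive Control 2, which entered no comparison, averaged 8855 units above the blank mean on the parental array and 15546.5 to 16703 on the clones. The 3 clones were derived from 1 selection, so the p-values measure only the spread between these samples.

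The main comparison asked which transcripts distinguish the resistant clones from the line they were selected from. All 38 interferon-stimulated genes tested were lower in all 3 clones, and 19 of them passed limma's threshold. Of 26 hypoxia response genes 22 were lower and 3 higher in all 3 clones, and 9 passed the threshold as lower. Both lists passed camera's test, and neither passed it with an estimated correlation (adjusted p = 0.579 and adjusted p = 0.563). Single genes rose, among them SLC7A11, ODC1 and RGS7. GPR65, a proton-sensing receptor, rose 84.8-fold, from a log2 signal of 0.96 on the parental array to a mean of 7.37 on the clones (log2 difference 6.41 ± 0.12). NDRG1, a gene that hypoxia and other stresses induce, was 22.2-fold lower in the clones (log2 difference −4.47 ± 0.14). TNFSF10, the death ligand TRAIL, was 19.1-fold lower (−4.25 ± 0.23). The sizes depend on the background correction: with normexp on the spot and background columns the log2 difference was 1.04 for GPR65, −4.03 for NDRG1 and −2.83 for TNFSF10.

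By limma, 674 of the 16592 genes passed an adjusted p of 0.05, 360 of them higher and 314 lower in the clones, and 638 of them were above the limit on all 4 arrays. After GPR65, the largest increases were those of EVI2A (log2 difference 4.09 ± 0.11), SOCS2 (3.97 ± 0.26), a feedback inhibitor of cytokine signalling, ANKRD1 (3.88 ± 0.31), SYT14 (3.84 ± 0.24), of the synaptotagmin family, and SLCO2A1 (3.57 ± 0.15), a prostaglandin transporter. PPP2R2C (3.48 ± 0.35), a regulatory subunit of protein phosphatase 2A, FJX1 (3.34 ± 0.20), RGS7 (3.33 ± 0.40), a regulator of G protein signalling, and ODC1 (3.33 ± 0.23), the rate-limiting enzyme of polyamine synthesis, completed the 10 largest. Parental log2 signals lay near the floor of 0.61 for SYT14 (1.14), EVI2A (1.64), PPP2R2C (1.88), ANKRD1 (1.98) and SLCO2A1 (1.99). They were 2.33 for SOCS2, 2.35 for RGS7, 3.94 for FJX1 and 7.15 for ODC1. The lowest log2 difference over the alternatives was 0.27 for PPP2R2C, 0.29 for SLCO2A1 and 0.34 for SYT14. It was 0.57 for RGS7, 0.61 for SOCS2, 0.96 for FJX1 and 2.87 for ODC1. After NDRG1 and TNFSF10, the largest decreases were those of TMEM140 (−4.25 ± 0.42), IFI44L (−4.07 ± 0.36), IFITM1 (−3.98 ± 0.48), RTP4 (−3.80 ± 0.31), GAL3ST1 (−3.79 ± 0.19), a sulfotransferase of sulfatide synthesis, EPSTI1 (−3.79 ± 0.37), TRIM22 (−3.74 ± 0.27) and CLEC7A (−3.72 ± 0.31), the beta-glucan receptor dectin-1. Adjusted p-values of these 20 genes lay between 0.0442 and 0.0495. PPP2R2C was at 1.35 without GR1 and at 1.51 without GR3, where another of its probes was the brightest, and at 2.44 with the mean of its probes.

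Some transcripts were above the limit on one side only. COX7B2, an isoform of a cytochrome c oxidase subunit, was at least 50.5-fold higher in the clones than the parental floor (adjusted p = 0.0481), TTLL7, a tubulin-modifying ligase, at least 7.23-fold and MYL2, a myosin light chain, at least 4.87-fold. AGTR1, the angiotensin II receptor, was at least 13.5-fold higher (adjusted p = 0.149) and the cytokine IL24 at least 4.92-fold (adjusted p = 0.243), and neither passed the test. GR3 lay lowest in both (2.75 for AGTR1 and 1.56 for IL24), and without it the bounds were 24.6-fold and 8.09-fold. In the other direction, LIPK was at least 9.65-fold lower, IL17A at least 4.71-fold, OR4N4 at least 4.49-fold, NXPE2 at least 4.39-fold and SNCAIP at least 2.38-fold, each with an adjusted p of 0.0442. These 5 genes have equal values at the floor on all 3 clones, which carry no spread of their own, and dim parental log2 signals of 3.88 or less. The bounds hold for the subtraction of the blank mean: with normexp on the spot and background columns the log2 difference was 0.45 for COX7B2, 0.22 for AGTR1, 0.18 for TTLL7, 0.0776 for IL24, 0.0320 for MYL2, −0.14 for LIPK, −0.0823 for IL17A and between −0.06 and −0.05 for the other 3.

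With any 1 clone left out, which leaves 1 residual degree of freedom, 0 genes passed (smallest adjusted p = 0.201 without GR1, 0.0768 without GR3 and 0.211 without GR4), while the median size of the log2 difference over the 120 genes past the threshold that this text names was 1.94, 2.03 and 1.98, against 2.04 with all 3. These 120 genes were picked for differences that the 3 clones share, so leaving out 1 clone could hardly move this median. The limma count was 0 with no filter on dim probes (smallest adjusted p = 0.0507), 146 with normexp on the spot and background columns, 208 with no normalization between arrays, 1020 with median scaling (68.8% of them higher, against 53.4%) and 2127 for genes above the limit on all 4 arrays. Normexp on the spot and background columns also shrank the differences in both directions, with EVI2A at 0.14, ANKRD1 at 0.38, GADD45A at 0.41, SLC7A11 at 0.63, GAL3ST1 at −0.80, CLEC7A at −1.28 and TMEM140 at −1.44. Over the 120 genes the median was 0.61 against 1.95 for the 59 that were higher and −1.11 against −2.07 for the 61 that were lower.

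A count by size alone set the parental array beside each clone. All 38 interferon-stimulated genes tested were at least 2-fold lower than on the parental array in all 3 clones, and GPR65, ODC1 and VIM at least 2-fold higher. The rule gave 1205 genes, 607 higher and 598 lower. This even split (50.4% higher) depends on the processing. The share was 62.6% with median scaling and 65.1% with no normalization. It was 40.5% with normexp on the spot and background columns and 37.0% with normexp on blank-subtracted signals and the offset. With GR1 in the parental array's place the rule gave 27 genes, with GR3 85 and with GR4 20. Of the 674 genes that limma called, 606 were among the 1205.

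**Figure D1:**
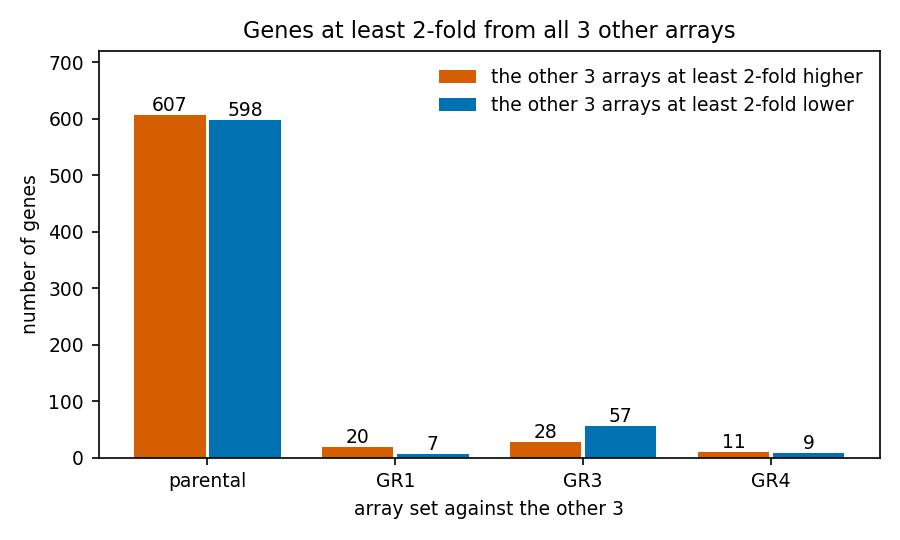
Number of genes (vertical axis) at least 2-fold from all 3 other arrays in the same direction, with each array in turn (horizontal axis) set against the other 3; orange bars count genes that the other 3 arrays have higher, blue bars genes that they have lower. The parental array has 607 and 598 such genes, and no clone has more than 57 in a direction.

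This rule has no test, because all comparisons share the 1 parental array. In 100 simulations of unchanged arrays that share it, the highest count was 24. These drew independent noise with the spread of the 3 clones, and so assume a parental array that varies like them. The real arrays gave 85 with GR3 in the parental place, above that simulated level. The count was 321 with normexp on the spot and background columns, 3083 at 1.5-fold and 382 at 3-fold.

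Of the 39 gene lists, 12 passed camera's test, 8 of them lower and 4 higher in the clones, and 0 passed with an estimated correlation. For hypoxia response genes the estimate was 0.0133, close to the preset 0.01, yet camera's unadjusted p went from 7.40e-09 to 0.0304. For the interferon-stimulated list the estimate was 0.756. For the hypoxia list, not passing with an estimated correlation therefore does not show that correlated genes explain the call. The estimate was also far above the preset for the stress response (0.424), mitosis (0.374), oxidative phosphorylation (0.231), immediate early (0.208) and histone (0.161) lists. It ran from −0.0236 to 0.0495 for the other called lists. Where it was high, the correlation also raises p, and its part was not separated from that of the few degrees of freedom. Interferon-stimulated genes had the largest shift, with a median log2 difference of −2.72 (6.60-fold lower) and each of the 38 tested members at least 2-fold lower in all 3 clones (adjusted p = 4.18e-20; adjusted p = 0.579 with an estimated correlation). Of these 38, 19 fell over all genes tested, and 38 fell when adjusted over the list alone. IRF9, a subunit of the transcription factor that drives these genes, fell by 2.07 ± 0.10 on the log2 scale, and the antiviral genes OAS1 and RSAD2 fell by 3.45 ± 0.23 and 3.51 ± 0.25. MHC class I antigen presentation was lower too, with a median of −0.83 over 16 genes (adjusted p = 2.45e-05; adjusted p = 0.563 with an estimated correlation). In that list 5 genes fell, 12 when adjusted over the list alone: HLA-E (−1.91 ± 0.12), HLA-F (−1.86 ± 0.13), PSMB9 (−1.56 ± 0.13), an immunoproteasome subunit, HLA-G (−1.46 ± 0.13) and TAP1 (−1.36 ± 0.12), the peptide transporter, which is named after its value was seen. HLA genes are similar in sequence, and hybridization of 1 gene to another's probe was not tested.

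Hypoxia response genes had a median of −1.03 over 26 genes (adjusted p = 1.44e-07; adjusted p = 0.563 with an estimated correlation), with 9 that fell (19 fell and 1 rose when adjusted over the list alone). NDRG1 led them, followed by MXI1 (−2.21 ± 0.15), a MYC antagonist, PFKFB4 (−2.19 ± 0.10) and KDM3A (−1.94 ± 0.11), a histone demethylase. Glycolysis had a median of −0.59 over 23 genes (adjusted p = 0.00294; adjusted p = 0.579 with an estimated correlation). PFKFB4, PFKFB3 (−2.13 ± 0.11), the neuronal enolase ENO2 (−1.55 ± 0.12), GPI (−1.14 ± 0.13) and PDK1 (−1.26 ± 0.15) fell and the lactate transporter SLC16A1 rose (1.28 ± 0.12), and over the list alone 12 fell and 3 rose; GPI and PDK1 are named after their values were seen.

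The lists of mitosis and DNA replication passed as higher in the clones, and that of cyclins and their regulators did not pass (adjusted p = 0.124). The mitosis list had a median of 0.62 over 32 genes (adjusted p = 1.54e-06; adjusted p = 0.639 with an estimated correlation). Of its members 0 passed limma over all genes and 12 rose when adjusted over the list alone; the anaphase activator CDC20 had a log2 difference of 1.69 ± 0.24 (adjusted p = 0.0541), and the mitotic genes KIF11, CENPF and KIF23 had 1.08, 0.90 and 0.82. DNA replication had a median of 0.56 over 43 genes (adjusted p = 1.82e-06; adjusted p = 0.563 with an estimated correlation). GINS2 (1.38 ± 0.12), CDC6 (1.31 ± 0.14), ORC6 (1.28 ± 0.13) and GINS3 (1.08 ± 0.12), which assemble or drive the replicative helicase, rose over all genes, and 16 rose and 1 fell over the list alone. The DNA damage checkpoint and homologous recombination list had a median of 0.33 over 43 genes (adjusted p = 0.000234; adjusted p = 0.579 with an estimated correlation). FANCB (1.26 ± 0.11), CLSPN (1.26 ± 0.11), RAD51C (1.17 ± 0.12) and RAD54B (1.13 ± 0.11) rose, 9 when adjusted over the list alone, and H2AX fell (−1.51 ± 0.13). RAD51C is named after its value was seen. Over the alternatives the log2 differences nearest 0 were 0.27 for FANCB, 0.41 for CLSPN, 0.19 for RAD51C, 0.40 for RAD54B and −1.19 for H2AX.

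The integrated stress response and unfolded protein response list had a median of 0.72 over 31 genes (adjusted p = 0.000246; adjusted p = 0.732 with an estimated correlation). Its 5 members that rose, 10 when adjusted over the list alone, were SLC7A11 (3.26 ± 0.35), the cystine transporter, PSAT1 (2.00 ± 0.17), of serine synthesis, TRIB3 (1.80 ± 0.19), CHAC1 (1.80 ± 0.20), which degrades glutathione, and SLC3A2 (1.35 ± 0.14), the partner chain of SLC7A11. CHAC1 is named after its value was seen. All 5 are known targets of the transcription factor ATF4.

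Histone genes had a median of −1.17 over 23 genes (adjusted p = 0.000102; adjusted p = 0.579 with an estimated correlation). H2BC21 (−1.93 ± 0.15), H2AC25 (−1.81 ± 0.19), H2AC6 (−1.81 ± 0.20), H2AX (−1.51 ± 0.13) and H3C1 (−1.22 ± 0.12) fell and H2AZ1 (0.99 ± 0.11) rose, and over the list alone 16 fell and 2 rose; H2AZ1 is named after its value was seen, and hybridization between related histone probes was not tested. Immediate early genes had a median of −0.48 over 24 genes (adjusted p = 0.00777; adjusted p = 0.665 with an estimated correlation), with NR4A1 (−3.32 ± 0.15) and EGR1 (−2.14 ± 0.24) past the test and DUSP1 and JUNB at −1.07 and −0.87; over the list alone 8 fell and 2 rose.

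Epithelial markers had a median of −0.36 over 29 genes (adjusted p = 0.0390; adjusted p = 0.579 with an estimated correlation). ELF3 (−2.54 ± 0.24), an epithelial transcription factor, and the tight junction gene TJP3 (−1.97 ± 0.11) fell, 7 fell and 2 rose when adjusted over the list alone, and CRB3 and CLDN7 had log2 differences of −1.0 and −0.73. Oxidative phosphorylation had a median of −0.19 over 57 genes (adjusted p = 0.0274; adjusted p = 0.830 with an estimated correlation), with 0 members past limma's test, also over the list alone, and log2 differences of −0.89 for NDUFB1 and −0.63 for NDUFB5, of which NDUFB5 was at 0.29 with normexp on the spot and background columns. Both calls were lost without GR1 (adjusted p = 0.0577 for the epithelial and 0.0954 for the oxidative phosphorylation list), and the epithelial call without GR3 (0.0834). With median scaling the epithelial adjusted p was 0.192 and the oxidative phosphorylation median was 0.05 (adjusted p = 0.990).

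**Figure D2:**
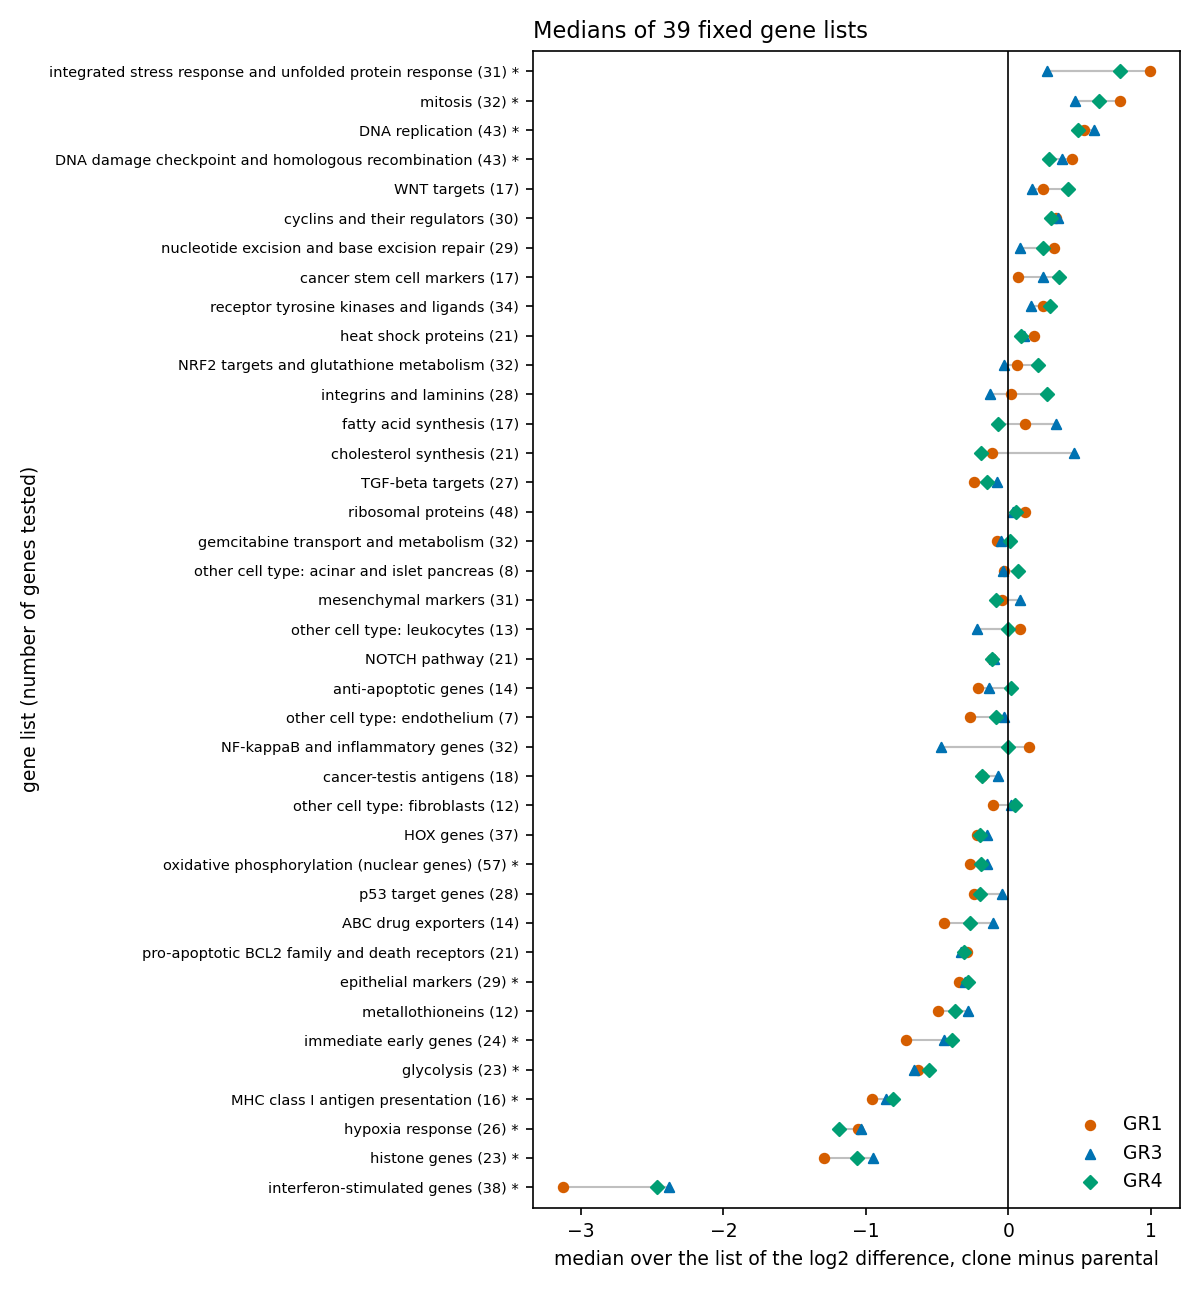
Median log2 difference from the parental array (horizontal axis) over the tested members of each of the 39 gene lists (vertical axis, number of genes in brackets), 1 point per clone; a star marks the 12 lists past camera's adjusted p of 0.05. Interferon-stimulated genes lie at −3.13 in GR1, −2.38 in GR3 and −2.47 in GR4, further from 0 than any other list.

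Gemcitabine transport and metabolism was the list closest to the selection. It did not pass, with members moving both ways: over 32 genes the median was 0.03, the mean −0.11 and the test's direction down (adjusted p = 0.938), and with median scaling the median was 0.17. NT5E, the ecto-nucleotidase CD73 that dephosphorylates extracellular AMP, rose 2.99-fold (log2 difference 1.58 ± 0.15), and UCK2, a uridine and cytidine kinase, rose 3.88-fold (1.95 ± 0.21). With normexp on the spot and background columns NT5E was at 0.50 (adjusted p = 0.829). NT5C3A, a cytosolic pyrimidine nucleotidase, fell by 2.04 ± 0.20, SAMHD1, which cleaves deoxynucleoside triphosphates, by 1.81 ± 0.19, and the transporter SLC29A4, named after its value was seen, by 1.13 ± 0.13. Over the list alone 7 rose and 7 fell. The nucleoside transporter SLC29A1 was 2.32-fold higher (1.21 ± 0.16, adjusted p = 0.0517), the concentrative transporter SLC28A3 2.77-fold lower (−1.47 ± 0.18, adjusted p = 0.0506) and the inactivating enzyme CDA 3.52-fold lower (−1.82 ± 0.33, adjusted p = 0.0692), each just short of the threshold. Over the alternatives the log2 differences nearest 0 were 0.31 for SLC29A1, −0.21 for SLC28A3, −0.13 for SLC29A4 and −0.71 for SAMHD1. They were −1.54 for CDA, 1.65 for UCK2 and −1.73 for NT5C3A. DCK, the kinase that activates gemcitabine, was at 0.51 ± 0.15 (adjusted p = 0.128), RRM1 at 0.60 ± 0.14 (adjusted p = 0.0959), RRM2 at 0.33 ± 0.14, RRM2B at 0.26 ± 0.18, DCTD at 0.37 ± 0.14, CMPK1 at 0.09 ± 0.16 and SLC28A1 at −0.22 ± 0.10, and none of them passed. CMPK1 was at −0.12 with normexp on the spot and background columns, and SLC28A1 at 0.04 with no normalization. NT5C2 lay near the floor on all 4 arrays, and no fold is given.

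**Figure D3:**
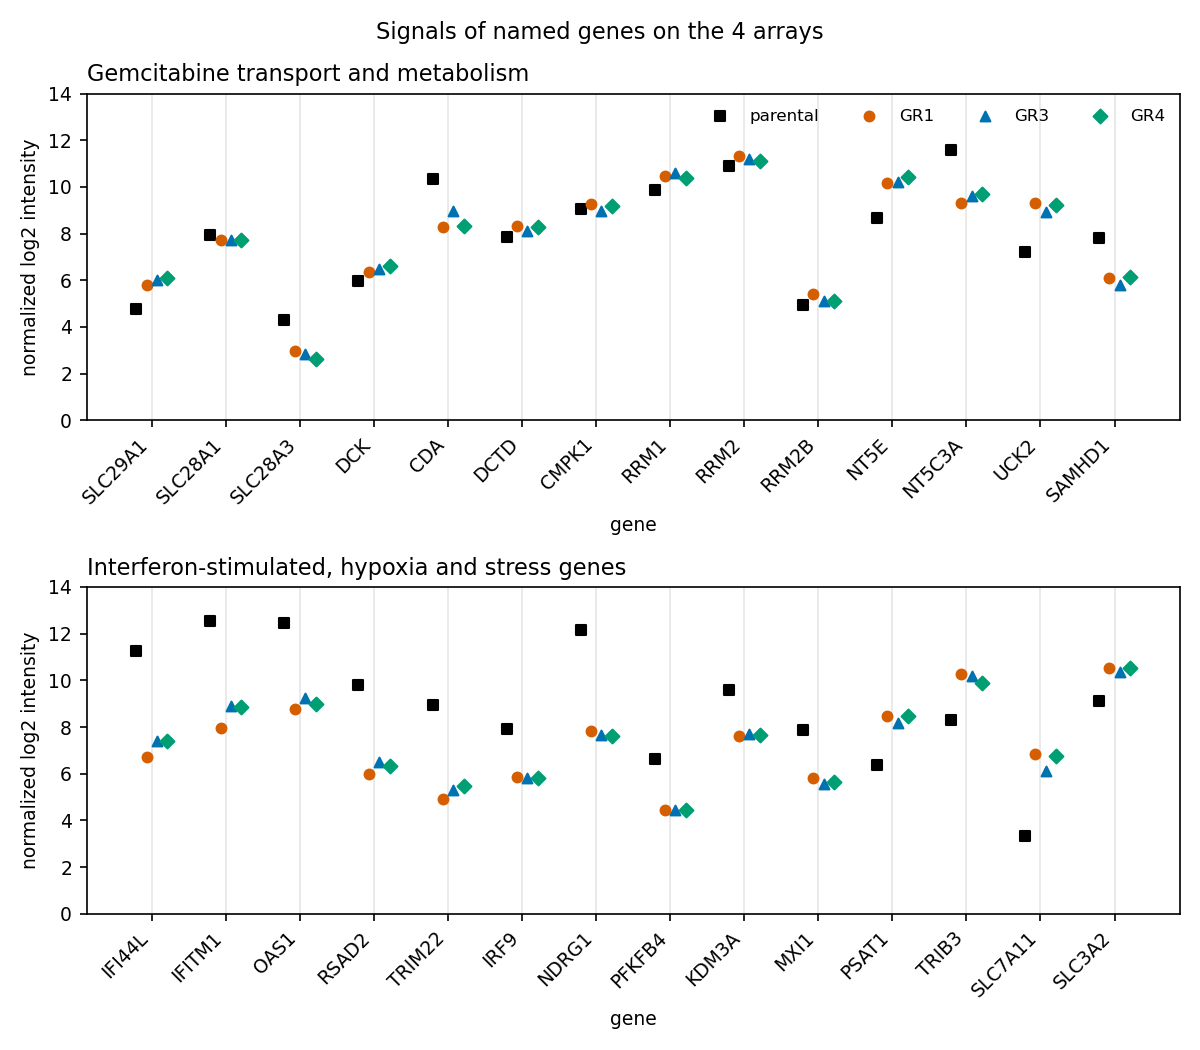
Normalized log2 intensity (vertical axis) of named genes (horizontal axis) on the parental array (black squares) and on the clones GR1, GR3 and GR4 (coloured points), 1 array per point, for gemcitabine handling above and for interferon-stimulated, hypoxia and stress response genes below. CDA lies at 10.34 on the parental array and at 8.28, 8.95 and 8.34 on the clones, and SLC7A11 at 3.33 against 6.86, 6.14 and 6.76.

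The other 26 lists did not pass either, and with the gemcitabine list their adjusted p ran from 0.0673 to 0.980. ABC drug exporters had 0 of 14 members past limma and a median of −0.28, with ABCC6 at −0.79, ABCC11 at −0.75, ABCC5 at 0.66 and ABCB1, at the floor on GR3 and GR4, at least 1.74-fold lower (adjusted p = 0.0854). Pro-apoptotic BCL2 family and death receptors had a median of −0.35 over 21 genes (adjusted p = 0.0673) and 0 members past limma (3 fell over the list alone), with BNIP3L at −1.96, BBC3 at −1.81, HRK at −0.94 and, named in advance, BOK at 0.22 (−0.24 with normexp on the spot and background columns). Among anti-apoptotic genes BCL2L1 rose (1.21 ± 0.14, and 0.18 at its lowest over the alternatives). Of the p53 targets, GADD45A (3.23 ± 0.13), AEN (2.16 ± 0.17) and PLK3 (0.85 ± 0.10) rose, and TP53INP1, near the floor on the clones, was at least 5.65-fold lower (adjusted p = 0.0442). Of the mesenchymal markers, the intermediate filament VIM (2.84 ± 0.17) and the receptor kinase AXL (1.71 ± 0.14) rose, and FN1, fibronectin, was at −3.41 ± 0.45 (adjusted p = 0.0517) and S100A4 at −1.0.

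Single members of further lists passed. CCNG2, an atypical cyclin linked to cell cycle arrest, fell by 2.04 ± 0.17, with CDK6 at 1.51 ± 0.19 (adjusted p = 0.0510), RBL2, of the retinoblastoma family, at −0.80 ± 0.11 (adjusted p = 0.0532) and CCND2 at 2.85 ± 0.49 (adjusted p = 0.0646). The WNT antagonist DKK1 (3.28 ± 0.15), the TGF-beta targets THBS1 (2.96 ± 0.18) and INHBA (1.11 ± 0.11), the NOTCH ligands JAG1 (2.38 ± 0.28) and DLL3 (1.58 ± 0.13), the integrins ITGA2 (1.52 ± 0.17) and ITGA6 (1.45 ± 0.15), the EGFR ligand TGFA (1.87 ± 0.22) and the ribosomal protein gene RPL32 (0.99 ± 0.11) rose. Over the alternatives their lowest log2 differences were 0.12 for RPL32, 0.15 for TGFA, 0.23 for DLL3, 0.32 for JAG1 and 0.59 for ITGA6. They were 1.01 for INHBA, 1.34 for ITGA2, 2.12 for THBS1 and 2.63 for DKK1. The metallothionein MT1X fell (−2.45 ± 0.27), and the inflammatory gene TNFAIP6, at the floor on all 3 clones, was at least 3.81-fold lower (adjusted p = 0.0442). Markers of leukocytes (13 tested), fibroblasts (12), endothelium (7) and acinar and islet cells (8) had 0 members past limma.

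With an estimated correlation 0 of the 39 lists passed, and with fry, which does not compare a list with other genes, 7 did. Among these, WNT targets and heat shock proteins had not been called by camera. Of camera's calls, the interferon-stimulated, histone, DNA damage, immediate early, mitosis, stress response and oxidative phosphorylation lists did not pass fry. Their adjusted p by fry ran from 0.0569 to 0.277. The interferon-stimulated list had an adjusted p of 0.0569 by fry.

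Each clone was then set against the parental array and against the other clones. The clones lay closer to one another than to the parental line, with the pair GR1 and GR4 closest. GR1 had 2246 genes at least 2-fold from the parental array (1151 higher, 1095 lower), GR4 2175 (1112 higher, 1063 lower) and GR3 1794 (921 higher, 873 lower). Between clones the counts were 470 for GR3 and GR1, 415 for GR4 and GR3, and 156 for GR4 and GR1. Across genes, which are not independent replicates, log2 signals correlated at 0.960 to 0.967 between a clone and the parental array and at 0.988 to 0.994 between clones.

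Some genes set 1 clone apart from all 3 other arrays. GR1 was higher in POPDC1, of the Popeye domain family (4.05 against 0.96 or less), CDH15, M-cadherin (2.85 against 1.64 or less), and SHISAL2A (4.34 against 2.83 or less), and lower in CFI, complement factor I (0.69 against 2.51 or more), FILIP1L (4.55 against 6.18 or more) and HPGD, which degrades prostaglandins (0.61 against 2.13 or more). GR3 was higher in the microfibril gene MFAP5 (6.75 against 3.45 or less), LMOD2, leiomodin (4.63 against 1.44 or less), and FGF13 (6.68 against 3.66 or less), and lower in S100A8, a calgranulin (1.92 against 4.43 or more), TCN1, a cobalamin carrier (3.75 against 5.94 or more), and SERPINB3 (3.89 against 5.90 or more). GR4 was higher in FAM120A2P (4.76 against 0.61), ZNF121 (6.95 against 4.93 or less) and PKD1L3 (3.09 against 1.44 or less), and lower in SIAE, a sialic acid esterase (0.61 against 5.71 or more), NME9 (5.49 against 6.79 or more) and DEFB110, a defensin (0.61 against 1.81 or more).

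These differences between single arrays have no test. With normexp on the spot and background columns S100A8, PKD1L3 and DEFB110 no longer set their clone apart, and the counts against the parental array were 703 for GR1, 678 for GR3 and 656 for GR4.

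The last comparison asked whether neighbouring genes moved together, since drug-selected clones can gain or lose chromosome segments. Along the 16492 genes that could be placed, 4 runs went beyond the random orders, 1 higher and 3 lower in the clones. The longest, 46 genes from TRIM38 to H3C11, covers histone and butyrophilin genes and had a strongest window median of −0.96; TRIM38 (−2.08 ± 0.16), BTN3A3 (−1.89 ± 0.21), H2AC6 and BTN3A1 (−1.65 ± 0.14) fell most. In a run of 26 genes from TRPC4 to ENOX1, with a strongest median of −1.02, EPSTI1, ELF1 (−1.90 ± 0.20), NHLRC3 (−1.81 ± 0.12) and MTRF1 (−1.62 ± 0.11) fell most. In a run of 25 genes from A2ML1 to KLRC1, which covers C-type lectin receptors, the median was −0.94; CLEC7A and KLRC4 (−2.69 ± 0.32) fell, CLEC2B, at the floor on GR3 and GR4, was at least 9.64-fold lower (adjusted p = 0.0442), and KLRK1 was at −2.31 ± 0.55 (adjusted p = 0.0968).

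The run that was higher in the clones holds 26 genes from TUBA3C to PABPC3, with a strongest median of 0.81. EEF1AKMT1 (2.15 ± 0.14), SKA3 (2.06 ± 0.16) and MRPL57 (1.54 ± 0.12) rose, and the Hippo pathway kinase LATS2 was at 1.47 ± 0.41 (adjusted p = 0.121). The window medians beyond which a run was counted were 0.78 and −0.72. With quantile, median, cyclic loess or no scaling, the strongest window of the run from TRIM38 ran from −1.03 to −0.63. That of the run from TRPC4 ran from −1.02 to −0.74, from A2ML1 −0.98 to −0.87 and from TUBA3C 0.776 to 0.873. The bounds belong to the main scaling.

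**Figure D4:**
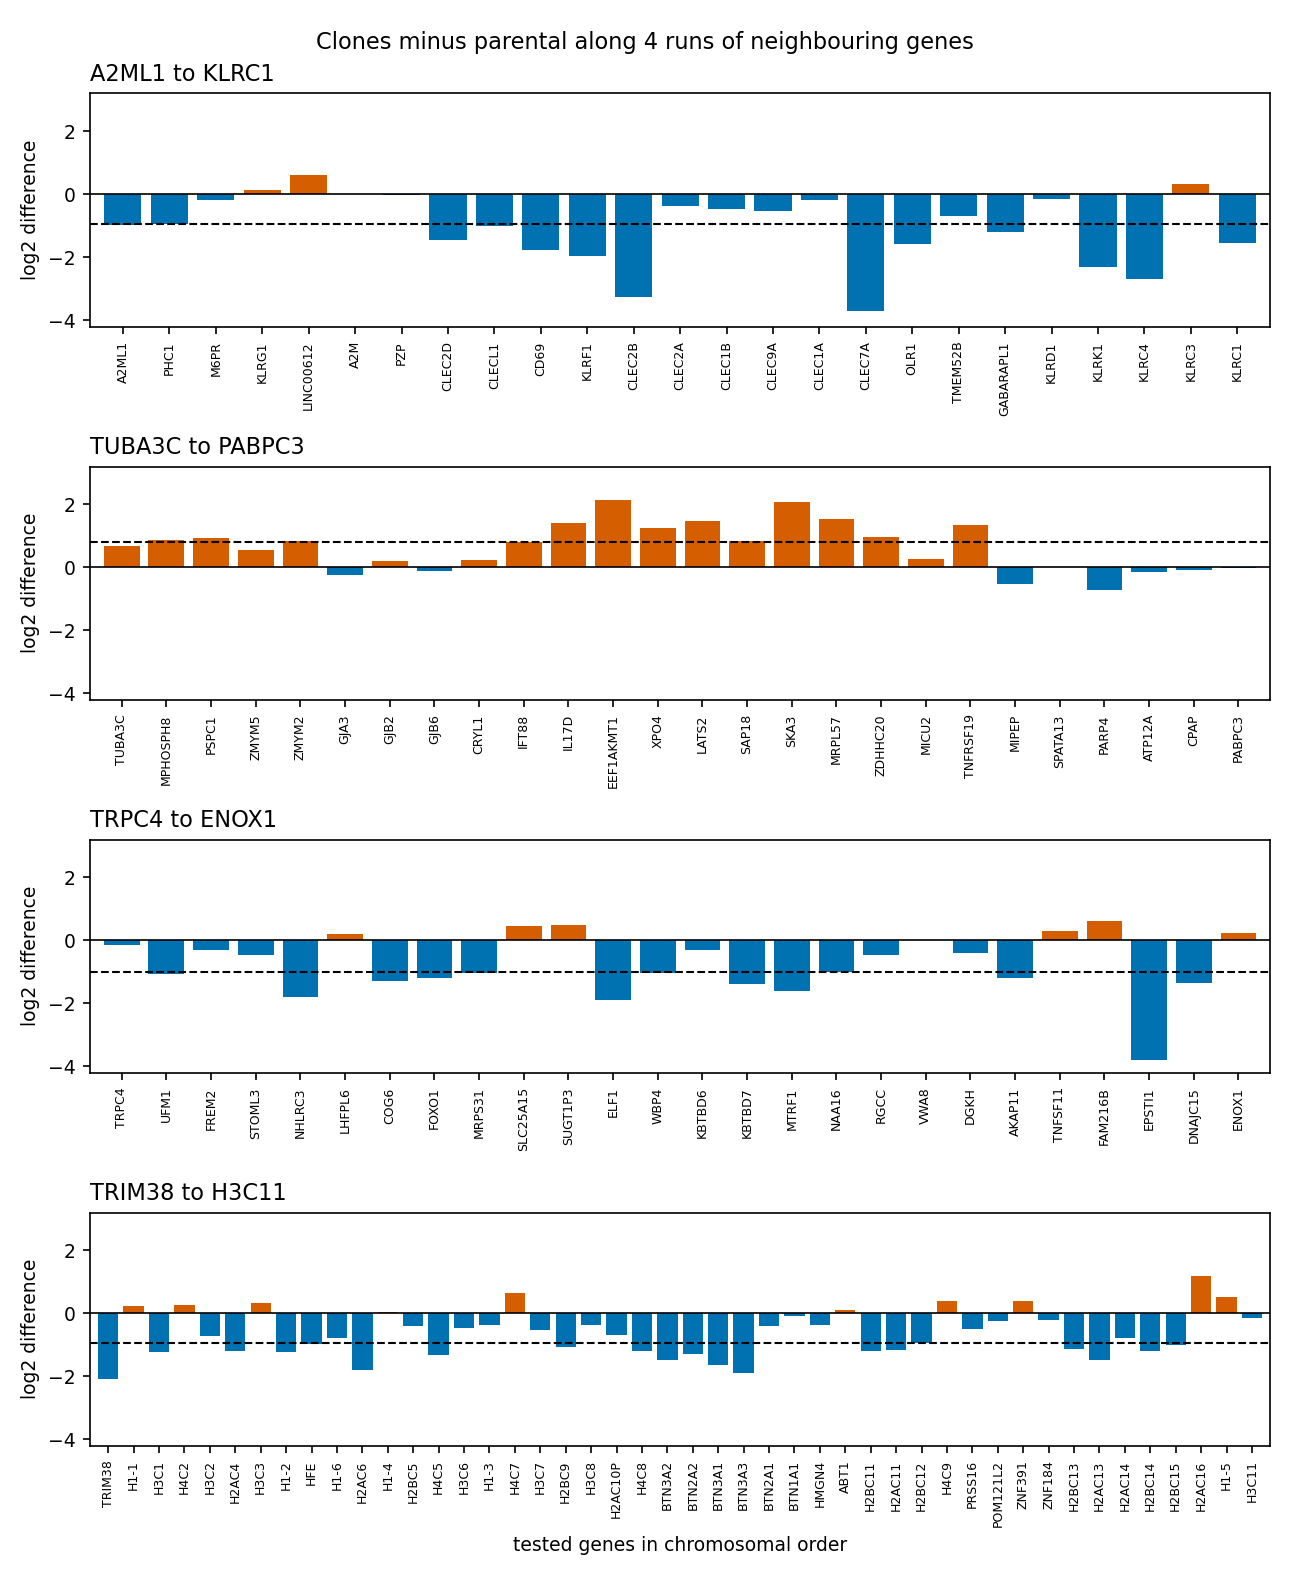
Log2 difference between the mean of the clones and the parental array (vertical axes) for each tested gene along the 4 runs, in chromosomal order (horizontal axes); orange bars are higher and blue bars lower in the clones, and the dashed line is the median of the run's strongest window. The medians are −0.94, 0.81, −1.02 and −0.96 from top to bottom, and members of every run lie on both sides of 0.

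When the clones were searched singly, 2 of the 4 runs went beyond the random orders in all 3 clones, those from A2ML1 to KLRC1 and from TRIM38 to H3C11. The run from TRPC4 to ENOX1 did so in GR3 and GR4, and the higher run, from TUBA3C to PABPC3, in 0 of the 3 clones. With windows of 15 genes 1 run was found. As a stand-in for families, nearby genes whose symbols share the first 3 letters were grouped, and histone genes likewise. With 1 gene kept per group 0 of the 4 runs remained. Such groups can join unrelated genes and miss relatives under other names.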

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

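The tests with cyclic loess, with the signal before scaling, over 4 scalings, with leukocyte markers and with genes that have no relative in a window were chosen only after the results they bear on were seen.

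The spots of Positive Control 2, a control probe outside every comparison, were looked at because they differed between the groups. Their mean above the blank was 8855 units on the parental array (SD 531 over 24 spots), and on the clones it ran from 15546.5 to 16703.

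The parental array stood apart from the 3 clones, with 1205 genes at least 2-fold from all other arrays against 85 or fewer for each clone. Cyclic loess, which removes a difference that follows brightness, left a count of 1134 against 89 or fewer, and the fullest of the 24 blocks of the array held 1.26 times as many of the 1205 genes as its share of tested genes would give (the emptiest 0.761 times), which speaks against a flaw of the surface as the whole cause. A lower yield on the parental array, as Positive Control 2 could reflect, would lower all its signals, but its median gene signal before scaling was 1.003 times that of the lowest clone, while the control stood at 0.570 times. The selection in gemcitabine, the passage through single cells, and the day of culture or of labelling stay open and were not tested, because the parental line has 1 array.

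The interferon-stimulated, hypoxia and glycolysis lists passed camera as lower and the mitosis and DNA replication lists as higher in the clones, and none passed with an estimated correlation (adjusted p from 0.563 to 0.639). The median of the interferon-stimulated list was −2.46 or further from 0 under all 4 scalings, and leukocytes among the parental cells, which would raise their own markers there, are argued against as the whole cause by a median of −0.0302 over 13 markers (lower quartile −0.44), although CD14 was at −1.44 (adjusted p = 0.0518). A denser parental culture may have contributed: targets of YAP, which dense cultures lower, had a median of 0.79 in the clones with 17 of 24 higher, from a list written when, of its members, the values of NT5E and FJX1 had been seen (without them, 0.69 with 15 of 22 higher). Higher YAP activity could equally belong to the resistant cells themselves, and neither this nor an effect of the selection was tested.

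Runs of neighbouring genes moved together in 4 places. With 1 gene kept per family, among 13555 genes in place of 16492, 0 of the 4 runs went beyond the random orders. Families were read from the opening letters of gene symbols, so relatives under other names counted as unrelated. Related genes are argued against as the cause of the runs from TRPC4 and from TUBA3C. There 23 and 21 of the 25 genes of the strongest window have no relative by symbol, so few members could owe their difference to one. Their medians were −1.02 and 0.84, which could hardly leave the window's median, because only 2 and 4 genes were left out. The 21 include GJA3, a connexin gene like GJB2 and GJB6. For the run from A2ML1, of lectin receptors, and that from TRIM38, of histones and butyrophilins, families stay open. Only 8 and 4 genes there have no relative by symbol (medians −0.81 and −0.31). The 8 include the lectin receptors CD69 (−1.78) and OLR1 (−1.58) and PZP, a relative of A2M, so fewer are truly unrelated. With dim genes left out, 1 run was left, that from TRIM38 to H3C11, so noise of dim probes may have shaped the others. Leaving out genes also changes which genes share a window, and no measure of DNA copy number was at hand, so gains or losses of segments stay open and untested.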

How the results depend on the processing

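Normexp on the blank-subtracted signals and the looser bounds for runs were added after seeing the data; the other alternatives were planned. The 1205 genes were picked for a 2-fold difference in each clone, so leaving out a clone cannot turn their sign and a scaling hardly can; 1192 kept it under normexp on the spot and background columns and 1204 with the mean of a gene's probes. Sizes moved more: over 120 named genes past the threshold the median size of the log2 difference was 2.04, and it was 0.88 with normexp on the spot and background columns (53 at least 2-fold, against 116) and 1.24 with normexp on blank-subtracted signals and the offset (76). Of 12 called lists, 10 passed camera under each of 13 alternatives, and 147 of 156 comparisons of a called list with an alternative passed (adjusted p from 2.20e-30 to 0.993). The 13 leave out the estimated correlation, where 0 of the lists passed, and fry, where several calls were lost. List medians ran from 0.24 to 0.91 for mitosis and from 0.23 to 0.83 for DNA replication. They ran from 0.13 to 0.45 for the DNA damage list and from −1.19 to −0.45 for histones. KIF23 was at 0.04 at its lowest. Of the 120 named genes past the threshold 0 reversed, over 1119 results that stayed past it and 670 that did not. Leaving out a clone or the filter on dim probes ended every call, and the other alternatives 190. The sizes held at a median of 1.94, 2.03 and 1.98 without GR1, GR3 and GR4 and 2.04 with no filter, where the smallest adjusted p was 0.0507. The fits without a clone have 1 residual degree of freedom, and other thresholds count other genes by construction; for the other settings the cause was not tested. Depth, on arrays the signal over background, limits genes near the floor of 1.52 units. No paired analysis was possible because the groups share fewer than 2 replicate numbers.

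The 674 limma calls became 0 without each clone in turn (0 at the lowest and highest), 0 with no filter, 146 with normexp on the spot and background columns, 208 with no normalization, 1018 with the authors' table, 1020 with median scaling, 1255 with an intensity trend, 1523 with a robust prior, 2127 for genes above the limit on all 4 arrays, 2165 and 2203 with normexp on blank-subtracted signals without and with the offset of 50, and 3230 at an adjusted p of 0.1. The 1205 genes became 321 with normexp on the spot and background columns, 413 with normexp on blank-subtracted signals with the offset, 3083 at 1.5-fold and 382 at 3-fold. The 12 lists became 0 with an estimated correlation. With fry 7 of the 39 lists passed, but WNT targets and heat shock proteins among these are not among the 12. Several of the 12, the interferon-stimulated list among them, did not pass fry. Cyclic loess added the pro-apoptotic list to camera's calls (adjusted p = 0.0459). Runs of neighbours were 1 with windows of 15 genes, 3 with 50, 4 with median scaling and 7 with bounds that 5% of the random orders pass.

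Between pairs of arrays, in the order GR1, GR3 and GR4 against parental and then GR3 with GR1, GR4 with GR1 and GR4 with GR3, the counts were 757, 567, 693, 83, 4 and 64 with normexp on blank-subtracted signals and the offset, 5318, 4700, 5249, 1870, 910 and 1718 at 1.5-fold, and 750, 586, 709, 120, 13 and 104 at 3-fold. With normexp on the spot and background columns they were 703, 678 and 656 against parental, 302 for GR3 with GR1 and 245 for GR4 with GR3. With no normalization GR4 and GR1 differed in 294 genes.

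Reversals were few. The median of the oxidative phosphorylation list turned to 0.0492 with median scaling, 0.0886 with no normalization and 0.0484 with the authors' table (adjusted p 0.874 to 0.993). For the gemcitabine list the direction of the test turned from down to up under the same 3 settings (adjusted p 0.822 to 0.874), while its median, 0.03, did not turn and was 0.17, 0.21 and 0.17. SLC28A1 was at 0.0382 with no normalization. With normexp on the spot and background columns NDUFB5 was at 0.29, CMPK1 at −0.12 and BOK at −0.24, and the gap that sets a clone apart was −0.00555 for S100A8, −0.0103 for PKD1L3 and −0.00266 for DEFB110 on the log2 scale. The cause of these reversals was not tested.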

Other observations

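The lists in this part were written after differences of single genes had been seen, so their tests are not independent of the data; of the YAP targets, those of NT5E and FJX1 had been seen. Genes of ribosome biogenesis, which process ribosomal RNA and assemble the subunits, had a median log2 difference of 1.11 over 62 genes (1.03 to 1.38 over 4 scalings; adjusted p = 4.78e-19 by camera, adjusted p = 0.116 with an estimated correlation). Over all genes tested 17 rose, among them UTP20 (2.41 ± 0.12), PNO1 (2.07 ± 0.20), NOLC1 (2.04 ± 0.20) and BYSL (2.02 ± 0.15). Transfer RNA synthetases and tRNA processing genes had a median of 0.70 over 31 genes (0.65 to 0.90 over the scalings; adjusted p = 3.39e-10, adjusted p = 0.116 with an estimated correlation). Of these 5 rose: METTL1 (2.05 ± 0.11), which methylates tRNA, FARSB (1.86 ± 0.14), RPP40 (1.84 ± 0.12), a subunit of RNase P, IARS1 (1.20 ± 0.14) and VARS1 (0.91 ± 0.11).

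Of 15 butyrophilin and TRIM genes, with a median of −1.34 (−1.34 to −1.23 over the scalings; adjusted p = 6.52e-08, adjusted p = 0.116 with an estimated correlation), 8 fell, among them TRIM21 (−2.25 ± 0.25) and TRIM38; TRIM22 belongs to the interferon-stimulated list and is not in this one. Interferon ligands, receptors and signalling genes had a median of −0.48 over 24 genes (−0.50 to −0.32; adjusted p = 0.000119, adjusted p = 0.116 with an estimated correlation), and 6 fell, among them the RNA sensor TLR3 (−2.91 ± 0.16), STING1 (−2.07 ± 0.23), IFNL3 (−2.06 ± 0.14), IL10RB (−1.38 ± 0.15), a receptor chain of the lambda interferons, and IFNL1 (−1.12 ± 0.12). MHC class II genes had a median of −1.35 over 12 genes (−1.35 to −1.30; adjusted p = 0.000286, adjusted p = 0.136 with an estimated correlation); 1 fell, HLA-DRB5 (−1.75 ± 0.19), and HLA-DPA1 and HLA-DRA were at −3.40 ± 0.69 (adjusted p = 0.0788) and −3.31 ± 0.50 (adjusted p = 0.0569). The NF-kappaB and inflammatory genes, a list fixed in advance, did not pass (adjusted p = 0.447). Over all the alternatives, not the scalings alone, single genes of this part shrank more. The values nearest 0 were −0.06 for IFNL1, −0.21 for IFNL3, −0.23 for HLA-DPA1, −0.28 for HLA-DRB5 and 0.30 for NOLC1. They were −1.11 for TLR3, −1.55 for TRIM21 and 0.89 for UTP20.

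Of the 24 targets of YAP, a transcriptional coactivator of the Hippo pathway, 6 rose and 18 did not pass (adjusted p = 0.000119 by camera, adjusted p = 0.116 with an estimated correlation). Beside ANKRD1, FJX1, AXL and NT5E these were NUAK2 (2.05 ± 0.24) and PTPN14 (1.21 ± 0.11), and the median of the list was 0.79 (0.66 to 0.96 over the scalings).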
